A study of Homo sapiens with 16 samples.

How the data were processed

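RNA abundance was measured in 16 samples of the human breast cancer cell line MCF7, 4 per group, in a design of 2 RNA fractions (total and polysomal) by 2 conditions (untreated, 0 min, and 10 nM estradiol for 60 min). Per the labels' protocols, polysomal RNA came from a sucrose gradient of 15% to 50%, and each RNA was labelled in a single colour and hybridized to an Agilent whole human genome array. Each scan was read with Agilent Feature Extraction (protocol GE1_107_Sep09), whose version is 10.7.3.1 per the file headers and 10.7.7.1 per the submitters' processing notes. The deposited raw files hold, per the file headers, for each spot a background-subtracted and spatially detrended signal intensity on a linear scale, the median foreground and background intensities, and marks for saturation, outliers and signal well above background. The values deposited in the series table are on a log2 scale, and per the submitters' processing notes and a comparison with the raw files they are quantile-normalized processed signals: all 16 columns have a median of 7.35, their sorted values differ by at most 0.0014, and each column correlates with the log2 processed signal of its array at 0.995 or above.

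The processed signal intensity was the starting point. Of 45015 spots on each array 43376 were not controls, and these held 41000 probes. Spots marked as non-uniform or population outliers were set missing, no spot was saturated, and spots of the same probe were averaged on the log2 scale. From each value the array's 75th percentile of the log2 signal was subtracted. Probes were given gene symbols through the accessions on the array and a table of RefSeq symbols of assembly GRCh38.p14. The array's own annotation names build hg18, and no coordinates were used. A symbol was found for 25398 probes (17240 symbols), and the 15602 probes without one stayed out of the gene tests. A probe was tested where it was well above background on all 4 arrays of at least 1 group, and the brightest such probe stood for its gene, which left 13659 genes. Among called genes with several probes, another probe went in the opposite direction for 128 of 394 genes in total RNA and 2 of 43 in polysomal RNA after estradiol, 22 of 71 in the interaction, and 394 of 1649 and 666 of 2094 in the comparisons of both fractions before and after estradiol.

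Means of the 4 groups were fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), and 5 contrasts were tested: estradiol against untreated in total RNA and in polysomal RNA, the difference of these responses (the interaction), and polysomal against total RNA in untreated and in estradiol-treated cells. P-values were adjusted by the Benjamini-Hochberg method within each contrast and called under 0.05. Gene lists, 31 in number, were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists within a contrast. The tests were repeated with an estimated correlation, under which none of the 34 camera calls passed, and with fry, which tests whether a list's genes move on balance in 1 direction and does not compare the list with other genes. Lists of transcripts encoded in mitochondria and of small RNAs held too few measured members to be tested. The genes named are, for each contrast, the 10 with the largest positive and the 10 with the largest negative log2 difference among those that passed and, except in the interaction, did not overlap between the groups' arrays, up to 4 members with the largest moderated statistic of each list described, and 12 genes chosen in advance, with XIST, Y-linked genes and features without a symbol left out. The contrasts, the tests, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

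Files were read with python 3.11.15 and pandas 2.3.3, with numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The procedure was tested on simulated data, in which true changes of 2 on the log2 scale were called for 97.0% of genes in total RNA, 95.5% in polysomal RNA and 90.9% in the interaction, and changes of 1 for 61.2%, 59.7% and 28.4%. In these tests 1.72%, 4.24% and 10.1% of the calls were false. The simulated noise was independent between genes, with the same spread of a gene on all arrays and no slide effect. The rates therefore describe the procedure under these conditions and not the real arrays. Arrays of a group correlated at 0.964 to 0.993. The first principal component held 48.4% of the variance and separated the fractions, and the next held 16.1%.

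The alternatives tried were other scalings of the arrays (the median, quantile normalization, cyclic loess, the deposited series table), normexp background correction with an offset of 50, other filters on dim probes, the mean of a gene's probes or each probe by itself, fits of only the groups compared, a block on the replicate number, array weights, a variance trend with a robust fit, a covariate for array brightness, stricter thresholds, and leaving out single arrays or the 4 dimmest.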

Results

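RNA abundance was measured in MCF7 cells, an established line of human breast cancer cells that carries the estrogen receptor, with 16 one-colour Agilent expression arrays. Per the labels, the cells were kept for 48 h in 0.5% charcoal-treated serum and were then left untreated (0 min) or given 10 nM estradiol, the natural ligand of that receptor, for 60 min. From each condition either total RNA or polysomal RNA, the RNA recovered with polysomes from a sucrose gradient, was put on arrays. The 4 groups (total untreated, total estradiol, polysomal untreated and polysomal estradiol) held 4 arrays each, numbered as biological replicates. The depth of an array shows in its brightness and in the share of its spots well above background. The 75th percentile of the processed signal lay between 1246 and 1614 in the total untreated arrays, between 457 and 1613 in the total estradiol arrays, between 873 and 3018 in the polysomal untreated arrays and between 718 and 2597 in the polysomal estradiol arrays. In the same order, 66.6% to 77.3%, 67.1% to 74.7%, 60.8% to 70.6% and 60.1% to 72.0% of the spots were well above background. The number of arrays limits the precision. All differences below are log2 differences with their standard errors from limma, n = 4 arrays per group, over 13659 genes tested. Adjusted p-values measure the spread between biological replicates as labelled. A gene named among the largest differences of a comparison of 2 groups had no overlap between the 4 arrays of each group. Where the dimmer group had no array with the gene well above background, the fold is written as a lower bound. It sets the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the gene's own signal and the lowest signal among probes well above background on that array. Each group lay on a slide of its own, total RNA was scanned on one day and polysomal RNA on another, and slide and group cannot be told apart. No group was left without estradiol for 60 min, since the untreated cells stood for 0 min. Differences after estradiol therefore cannot be told apart from those of elapsed time and handling. The quality summary in the raw files read ExtractionEvaluate on every polysomal array and ExtractionInRange on every total RNA array.

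The comparison of total RNA with and without estradiol asks which transcripts changed in abundance within 60 min. GADD45B, a stress-induced gene of growth arrest, rose 4.42-fold (log2 2.14 ± 0.17, limma adjusted p = 1.01e-05), and VASN, which encodes vasorin, a binder of TGF-beta, rose 7.47-fold (2.90 ± 0.33, adjusted p = 0.000278). SNAI1, the repressor of E-cadherin, rose 4.19-fold (2.07 ± 0.19, adjusted p = 4.92e-05), and SGK1, a serum- and glucocorticoid-induced kinase, rose 3.34-fold (1.74 ± 0.24, adjusted p = 0.000969). The classical early targets MYC and FOS rose by 0.81 ± 0.24 (1.75-fold, adjusted p = 0.0415) and 1.44 ± 0.30 (2.72-fold, adjusted p = 0.0105). TRIB1, a pseudokinase, fell by 1.05 ± 0.16 (2.07-fold, adjusted p = 0.00184).

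In total RNA 527 genes were higher and 948 lower after estradiol at an adjusted p under 0.05, and 418 of the former and 768 of the latter differed at least 1.5-fold. Among the largest increases were also ASB2, a substrate receptor of a ubiquitin ligase (at least 5.07-fold higher), the chemerin receptor CMKLR1 (at least 2.92-fold higher), the anthrax toxin receptor ANTXR2 (at least 2.80-fold higher), the plasma glycoprotein AHSG (6.05-fold, 2.60 ± 0.47), the nicotinic receptor subunit CHRNA6 (2.22 ± 0.51), the phosphodiesterase PDE5A (2.20 ± 0.57), the pepsinogen PGC (2.17 ± 0.28) and the orphan nuclear receptor NR0B2 (2.13 ± 0.54). The largest decreases were those of the myosin MYO3A (-2.69 ± 0.72), FCRLA (at least 2.60-fold lower), the restriction factor TRIM5 (-2.18 ± 0.43), the calcium channel subunit CACNG2 (-2.16 ± 0.49), the epidermal gene LCE2B (-1.95 ± 0.23), the connexin GJA3 (-1.93 ± 0.30), POPDC3 (-1.86 ± 0.22), LRRC32 (-1.80 ± 0.38), the relaxin family receptor RXFP4 (-1.80 ± 0.23) and UBQLN4 (-1.69 ± 0.41). None of these 10 was well above background on all 4 estradiol arrays, so their sizes and ranks rest in part on the background. Among the increases, PGC was well above background on only 2 of the 4 total untreated arrays, which limits its size and rank likewise. For NR0B2 and PDE5A, array 4 of the total untreated group lay apart from the others of that group.

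Of 44 measured estradiol-induced genes, a list fixed from textbook knowledge, 8 rose, 3 fell and 33 did not pass in total RNA (9 up and 3 down adjusted over the list alone). KLF10, a TGF-beta-induced repressor, rose by 0.73 ± 0.16, and IGFBP4, a binder of insulin-like growth factors, fell by 0.67 ± 0.14. The list as a whole did not pass limma's camera test (median 0.27, adjusted p = 0.130, and adjusted p = 0.920 with an estimated correlation). Among 42 immediate early genes 7 rose, 3 fell and 32 did not pass (10 up and 4 down adjusted over the list alone), and FOSL2, a member of the AP-1 family, fell by 0.72 ± 0.15. That list did not pass either (median 0.23, adjusted p = 0.128, and adjusted p = 0.920 with an estimated correlation). The genes chosen in advance that did not pass were ESR1, the estrogen receptor itself (-0.25 ± 0.14), GREB1 (0.30 ± 0.28), the progesterone receptor PGR (-0.75 ± 0.28), TFF1 (0.85 ± 0.38), EGR3 (0.91 ± 0.37), cyclin D1, CCND1 (-0.18 ± 0.14), SIAH2 (0.28 ± 0.22), CXCL12 (-0.04 ± 0.14), CCNG2 (0.11 ± 0.18) and ERBB2 (0.50 ± 0.23).

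The 79 cytosolic ribosomal protein genes had a median of 0.54 in total RNA. Of these 3 rose, RPL36AL (0.81 ± 0.22), RPL37 (0.85 ± 0.26) and RPS23 (0.83 ± 0.25), 76 did not pass, and none passed adjusted over the list alone (camera adjusted p = 1.70e-07, and adjusted p = 0.920 with an estimated correlation). Of 74 nuclear genes for oxidative phosphorylation 8 rose, among them NDUFB3 (0.74 ± 0.16), 2 fell, among them UQCRC1 (-0.51 ± 0.13), and 64 did not pass, with 8 up and 2 down adjusted over the list alone. Their median was 0.30 (camera adjusted p = 0.000112, and adjusted p = 0.920 with an estimated correlation). Of 75 mitochondrial ribosomal protein genes 3 rose, among them MRPL52 (0.70 ± 0.17), 1 fell, MRPL2 (-0.62 ± 0.13), and 71 did not pass, with 2 up and 1 down adjusted over the list alone. The list had a median of 0.15 (camera adjusted p = 0.0266, and adjusted p = 0.920 with an estimated correlation). Under quantile normalization these 3 lists lost their calls, with adjusted p-values of 0.147, 0.147 and 0.500 and medians of 0.03, 0.05 and 0.02. With fry their adjusted p-values were 0.283, 0.178 and 0.203. The difference in total RNA also ran with brightness over all genes. Of 8 equal bins by signal, the brightest had a median of 0.29 (77 genes higher, 16 lower). Bin 3 from the dim end had -0.13 (46 higher, 183 lower). These lists were not compared with genes of like brightness. The call of the mitochondrial ribosomal proteins was also lost without array 3 or 4 of the total estradiol group (0.0751 and 0.0671) or array 1 or 2 of the total untreated group (0.0629 and 0.0627). Of 56 replication-dependent histone genes 5 rose, among them H2BC5 (0.64 ± 0.16), 51 did not pass and none passed adjusted over the list alone. Members had a median of 0.25 (camera adjusted p = 0.000112, and adjusted p = 0.920 with an estimated correlation and 0.181 with fry). Of 19 aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 4 fell, namely YARS1 (-1.08 ± 0.16), AARS1 (-0.72 ± 0.16), VARS1 (-0.91 ± 0.21) and QARS1 (-1.0 ± 0.27), and 15 did not pass, with 7 down adjusted over the list alone. Their median was -0.33 (camera adjusted p = 0.0266, and adjusted p = 0.920 with an estimated correlation, 0.0554 on ranks and 0.0745 without array 2 of the total estradiol group).

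The count in total RNA was 60 with normexp background correction of the median signal and the 75th percentile, against 1475. With normexp and quantile normalization it was 1687, and without the 4 dimmest arrays it was 170. It was 3310, 468 and 509 without arrays 1, 2 and 4 of the total estradiol group and 541 to 692 without single total untreated arrays. Array weights gave 7411 genes and turned the majority, with 3951 higher and 3460 lower. MYC did not pass in total RNA, with adjusted p-values between 0.0502 and 0.122, when array 1, 2 or 4 of the total estradiol group, array 1, 2 or 3 of the polysomal estradiol group or any total untreated array was left out. It was lost in 9 of 15 other settings too, quantile normalization and median scaling among them. Fits without single arrays also lost the calls of CACNG2, CHRNA6, H2BC5, MRPL52, MYO3A, NR0B2, PDE5A, QARS1, RPL36AL, RPL37, RPS23, UBQLN4, UQCRC1 and VARS1 in total RNA, with adjusted p-values of at most 0.122 in up to 12 of 16 fits.

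The comparison of polysomal RNA with and without estradiol asks which transcripts changed in abundance on polysomes within 60 min. EGR3, a zinc finger transcription factor of the early growth response family, rose 9.44-fold (3.24 ± 0.37, limma adjusted p = 0.000133), SGK1 rose 7.02-fold (2.81 ± 0.24, adjusted p = 8.06e-06), and the forkhead factor FOXC1 rose 5.6-fold (2.48 ± 0.17, adjusted p = 1.31e-06). SNAI1 rose 5.45-fold (2.45 ± 0.19, adjusted p = 3.37e-06) and NR0B2 was at least 5.10-fold higher (adjusted p = 0.00469). PTGER4, a receptor for prostaglandin E2, fell 3.44-fold (-1.78 ± 0.27, adjusted p = 0.00214), and TNFRSF11B, which encodes the decoy receptor osteoprotegerin, fell 2.93-fold (-1.55 ± 0.17, adjusted p = 0.000105).

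In polysomal RNA 112 genes were higher and 32 lower, and 109 and 29 of them differed at least 1.5-fold. The other largest increases were those of VASN (3.05 ± 0.33, 8.27-fold), SMTNL2 (2.47 ± 0.32), the beta-1 adrenergic receptor ADRB1 (2.46 ± 0.41), DMRT2 (2.32 ± 0.32) and the semaphorin SEMA3G (2.25 ± 0.30). SMTNL2 was well above background on only 2 and EGR3 on 3 of the 4 polysomal untreated arrays. Their sizes and ranks therefore rest in part on the background. The other largest decreases were those of SPRY1, an inhibitor of growth factor receptor signalling (-1.71 ± 0.27), TRIB1 (-1.47 ± 0.16), MEX3B (-1.29 ± 0.16), SIX4 (-1.20 ± 0.16), the protocadherin PCDH10 (-1.15 ± 0.22), the MAP kinase phosphatase DUSP1 (-1.02 ± 0.16), the thioredoxin-binding protein TXNIP (-1.01 ± 0.22) and HIC2 (-0.97 ± 0.13).

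Of the 44 estradiol-induced genes 12 rose, none fell and 32 did not pass in polysomal RNA (20 up and 1 down adjusted over the list alone). The members that rose included MYC (1.53 ± 0.24, adjusted p = 0.00250), FOS (1.85 ± 0.30, adjusted p = 0.00319), the ubiquitin ligase SIAH2 (1.28 ± 0.22, adjusted p = 0.00541), the chemokine CXCL12 (0.76 ± 0.14, adjusted p = 0.00848), CCND1 (0.67 ± 0.14, adjusted p = 0.0217) and PMAIP1, a promoter of apoptosis (1.44 ± 0.18). The list passed the camera test with a median of 0.51 (adjusted p = 3.02e-13, and adjusted p = 0.130 with an estimated correlation). Of 42 immediate early genes 9 rose, among them the pluripotency factor KLF4 (1.5 ± 0.14) and GADD45B (1.62 ± 0.17), 2 fell and 31 did not pass, with 11 up and 6 down adjusted over the list alone. As a list they had a median of 0.14 (camera adjusted p = 0.00594, and adjusted p = 0.683 with an estimated correlation, 0.304 on ranks, 0.0765 with fry and 0.126 without array 2 of the polysomal untreated group). Of 20 genes reported to fall with estradiol, the Notch target HES1 rose by 1.74 ± 0.17 in polysomal and by 1.05 ± 0.17 in total RNA, and TXNIP fell in polysomal RNA (lost in 10 of 16 fits without single arrays, adjusted p up to 0.135). That list did not pass in polysomal RNA (1 up, 1 down, 2 up and 5 down adjusted over the list alone, median -0.10, adjusted p = 0.544, and adjusted p = 0.917 with an estimated correlation). ESR1 (-0.34 ± 0.14), GREB1 (-0.25 ± 0.28), PGR (-0.01 ± 0.28), TFF1 (0.39 ± 0.38), CCNG2 (-0.61 ± 0.18) and ERBB2 (0.07 ± 0.23) did not pass.

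**Figure D1:**
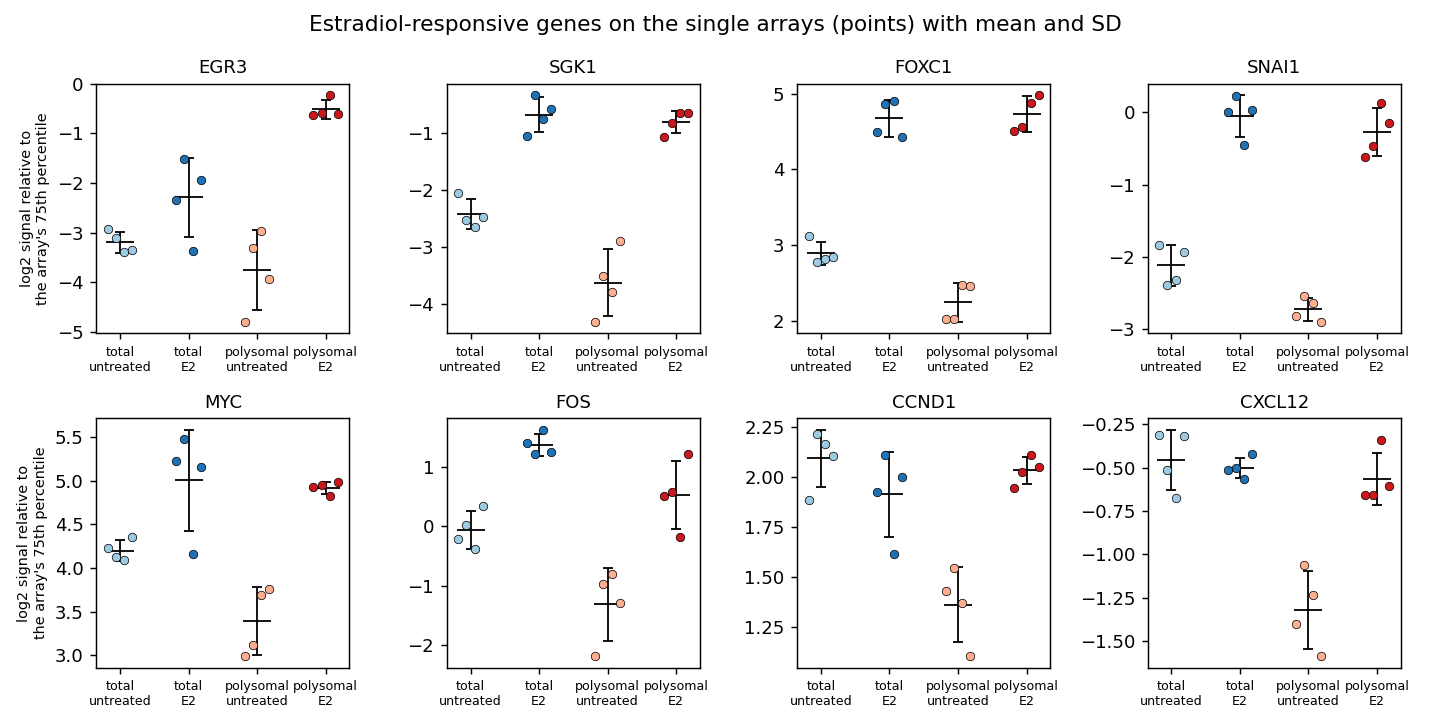
The 8 panels show the log2 signal of EGR3, SGK1, FOXC1, SNAI1, MYC, FOS, CCND1 and CXCL12 relative to each array's 75th percentile, with 1 point per array and the mean and SD of the 4 arrays of each group. In the 2 polysomal groups EGR3 differs by 3.24 and CXCL12 by 0.76, against 0.91 and -0.04 in the 2 total RNA groups.

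Of the 56 histone genes 1 rose in polysomal RNA, H3C11 (1.08 ± 0.20), and 55 did not pass, with 2 up adjusted over the list alone. These genes had a median of 0.23 (camera adjusted p = 2.21e-07, and adjusted p = 0.683 with an estimated correlation and 0.330 with fry). None of the 79 cytosolic ribosomal protein genes passed, singly or adjusted over the list alone, but all 79 lay above 0 with a median of 0.30 (camera adjusted p = 5.01e-07, and adjusted p = 0.917 with an estimated correlation and 0.700 with fry). None of 20 long non-coding RNAs passed, singly or adjusted over the list alone, with a median of 0.42 (camera adjusted p = 1.09e-06, and adjusted p = 0.472 with an estimated correlation and 0.0765 with fry). Without array 4 of the polysomal estradiol group the ribosomal protein list had an adjusted p of 0.324.

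The count of 144 in polysomal RNA was 50 with normexp correction of the median signal and the 75th percentile, and 119 with normexp and quantile normalization. It was 75 when the 8 polysomal arrays were fitted alone. Without array 3 of the polysomal estradiol group it was 94, and without array 3 of the total estradiol group 263. With array weights it was 4094, and the majority turned to 1707 higher and 2387 lower. CCND1 did not pass, with adjusted p-values between 0.0585 and 0.0797, without array 2, 3 or 4 of the polysomal estradiol group or array 3 or 4 of the polysomal untreated group. TXNIP did not pass without array 1, 2 or 3 of the polysomal estradiol group (0.110, 0.135 and 0.122), array 1, 3 or 4 of the polysomal untreated group (0.0663, 0.0992 and 0.0940) or any total untreated array (0.0531 to 0.0611). PCDH10 did not pass without array 3 of the polysomal untreated group (0.0611).

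The comparison of both responses asks whether estradiol changed polysomal RNA differently from total RNA, and was tested as the interaction of treatment and fraction. CCND1, the cyclin of G1, had a higher response in polysomal RNA by 0.85 ± 0.19 (limma adjusted p = 0.0321), CXCL12 by 0.80 ± 0.19 (adjusted p = 0.0402), EGR3 by 2.33 ± 0.52 (adjusted p = 0.0314) and IGFBP4 by 1.23 ± 0.19 (adjusted p = 0.00525). KLF4 (1.03 ± 0.20, adjusted p = 0.0150), FOSL2 (0.98 ± 0.21, adjusted p = 0.0235) and the small MAF factor MAFF (1.30 ± 0.21, adjusted p = 0.00546) did so too. IGFBP4 and FOSL2 were called lower in total RNA, so their differences include that fall. The responses of MYC (0.72 ± 0.34, adjusted p = 0.220), FOS (0.41 ± 0.42, adjusted p = 0.576) and SIAH2 (0.99 ± 0.31, adjusted p = 0.0892) did not differ past the threshold.

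In all, 246 genes had a higher and 80 a lower response in polysomal than in total RNA. Of the 246, 196 were genes called lower in total RNA and 37 were genes called higher in polysomal RNA, and 53 of the 80 were called higher in total RNA, in tests that share their arrays with the interaction. The 10 genes with the largest positive fitted differences were FCRLA, CHRNA1 (the muscle nicotinic receptor subunit), PCDHB1, EDDM3B, GJA3, NINJ2, the neurotrophic factor CNTF, RXFP4 (2.50 ± 0.33), SMTNL2 (2.46 ± 0.46) and KCNG3 (2.39 ± 0.42). The 10 with the largest negative ones were CDH23, CMKLR1, the kinase POMK (-2.75 ± 0.60), SLC9B1, PGC, CGB2 (-2.12 ± 0.46), SLC9B2 (-2.04 ± 0.50), MAPK8IP3 (-1.96 ± 0.43), LPA (-1.78 ± 0.41) and the corticotropin-releasing hormone receptor CRHR2 (-1.76 ± 0.30). No size is given where at least 1 group had no array well above background, since the fitted value and the rank then rest on the background. Of these 20 genes only CHRNA1, CRHR2, CGB2 and SMTNL2 were well above background on all 8 total RNA arrays, and none was so on all 16 arrays.

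Of the 44 estradiol-induced genes 6 had a higher response in polysomal RNA, none a lower one and 38 did not pass (8 up adjusted over the list alone). The list had a median difference of 0.26 (camera adjusted p = 0.0252, and adjusted p = 0.988 with an estimated correlation). That call was also lost with camera on ranks (adjusted p = 0.0501) and with fry (0.385). It was lost as well without array 1 or 3 of the total estradiol group (0.0615 and 0.0979), array 3 or 4 of the polysomal estradiol group (0.0739 and 0.0698), array 1 or 4 of the total untreated group (0.0692 and 0.0719) or array 1 of the polysomal untreated group (0.0679). None of the 74 genes for oxidative phosphorylation passed, singly or adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0252, and adjusted p = 0.988 with an estimated correlation), and that call was lost under quantile normalization (adjusted p = 0.293) and with fry (0.741). It was also lost without array 3 of the total estradiol group (0.220), array 1 or 2 of the polysomal estradiol group (0.118 and 0.0511), array 1 or 2 of the total untreated group (0.0692 and 0.0519) or array 1 of the polysomal untreated group (0.0679).

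Across the 13659 genes, which are not independent replicates, the log2 responses in total and polysomal RNA had a Pearson correlation of 0.083 and a Spearman correlation of 0.025. The 2 comparisons share no array. Both called 44 genes higher, where independent lists would share 4.32, among them GADD45B, SNAI1, SGK1, FOXC1 and HES1. Both called 4 genes lower, namely SPRY1, TNFRSF11B, TRIB1 and TBC1D25 (the last named after its values were seen), where independent lists would share 2.22, and 8 genes had calls in opposite directions against 9.01. Among the 112 genes higher in polysomal RNA 79 lay above 0 in total RNA. Over the 144 genes called in polysomal RNA the correlation of both responses was 0.53, on genes chosen by 1 of the 2 values.

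**Figure D2:**
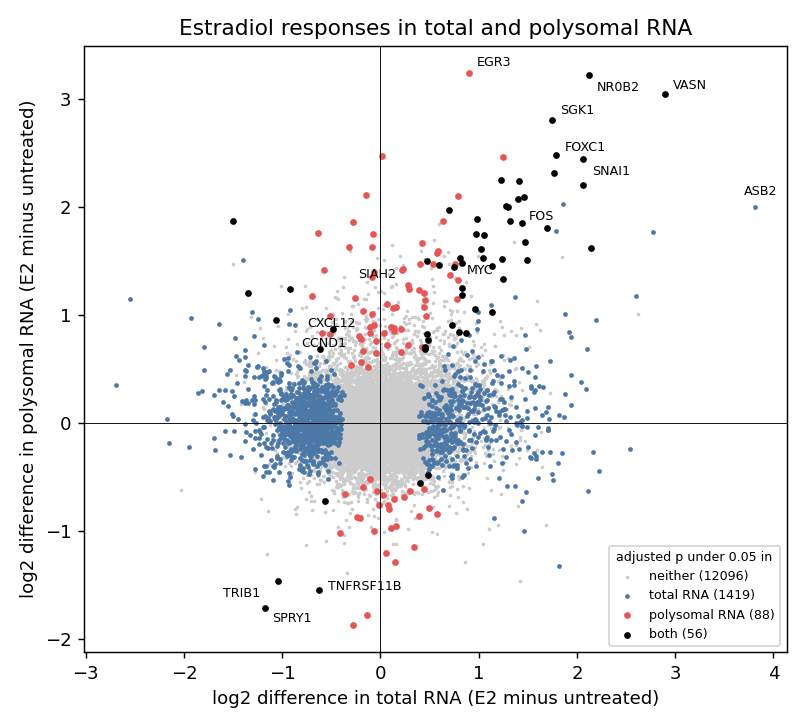
Each point is 1 of the 13659 genes, with its log2 estradiol difference in total RNA on the horizontal axis and in polysomal RNA on the vertical axis. Colours mark 1419 genes called in total RNA alone, 88 in polysomal RNA alone, 56 in both and 12096 in neither, and the correlation across genes is 0.083.

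The interaction had 1 call with normexp correction of the median signal and the 75th percentile, against 326. With normexp and quantile normalization it had 195 higher and 110 lower calls. Leaving out single arrays gave 114 to 1129. Under median scaling the majority turned, with 184 higher and 251 lower, and with array weights it was 3237 higher and 4042 lower. Fits without single arrays lost the called differences of CXCL12 (13 of 16 fits, adjusted p 0.0530 to 0.0856), CCND1 (7 fits, 0.0547 to 0.0773), EGR3 (7 fits, 0.0503 to 0.0681) and FOSL2. FOSL2 was lost without array 2 or 4 of the total estradiol group (0.0507 and 0.0546), array 2 of the polysomal estradiol group (0.0569) or array 1 or 3 of the total untreated group (0.0521 and 0.0607). CXCL12 was also lost in 8, and CCND1, EGR3 and FOSL2 in 3 each, of the other settings. Of the 20 genes with the largest fitted differences, PCDHB1, NINJ2, CDH23, CMKLR1, POMK, SLC9B1, CGB2, SLC9B2, MAPK8IP3 and LPA lost their calls in 3 to 11 of these fits.

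The comparison of polysomal with total RNA in untreated cells describes which transcripts had higher or lower relative signal in polysomal RNA before treatment. Loading onto polysomes cannot be told apart from slide and scan day here. LTB, which encodes lymphotoxin beta, was 61.4-fold lower in polysomal RNA (-5.94 ± 0.17, limma adjusted p = 1.97e-12), complement factor B, CFB, was 33.1-fold lower (-5.05 ± 0.34, adjusted p = 2.10e-07) and the acute phase protease inhibitor SERPINA3 was 21.0-fold lower (-4.40 ± 0.33, adjusted p = 5.58e-07). BIRC3, an inhibitor of apoptosis, was at least 12.2-fold lower (adjusted p = 9.70e-06). CAV1, the coat protein of caveolae, was 9.17-fold higher (3.20 ± 0.25, adjusted p = 7.96e-07), NCF2, a subunit of the NADPH oxidase, was 10.5-fold higher (3.39 ± 0.33, adjusted p = 3.80e-06) and the histone gene H4C1 was 7.56-fold higher (2.92 ± 0.19, adjusted p = 2.10e-07).

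In untreated cells 2379 genes were higher and 3298 lower in polysomal RNA. The other largest positive differences were those of the cysteine dioxygenase CDO1 (at least 4.13-fold), VGLL1 (at least 6.03-fold), SEMA3D (at least 3.65-fold), COX7B (2.71 ± 0.22), the growth factor TGFB2 (2.67 ± 0.27), LUZP2 (2.57 ± 0.39) and SERPINA11 (2.56 ± 0.31). The other largest negative differences were those of CHRNA1 (at least 4.81-fold lower), the costimulatory molecule CD86 (at least 6.82-fold lower), TRPC2 (at least 6.93-fold lower), EDDM3B (at least 4.40-fold lower), the prostacyclin synthase PTGIS (at least 3.20-fold lower) and WFDC11 (at least 2.72-fold lower).

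Higher in polysomal RNA were 38 of 56 replication-dependent histone genes, among them H4C12 (2.11 ± 0.16), H2AC21 (2.31 ± 0.18) and H4C11 (1.70 ± 0.14). Of the rest 1 was lower and 17 did not pass, with 41 up and 1 down adjusted over the list alone. Across the list the median was 0.66 (camera adjusted p = 2.93e-14, and adjusted p = 0.260 with an estimated correlation). Of 74 nuclear genes for oxidative phosphorylation 36 were higher, among them ATP5ME (1.58 ± 0.13), NDUFA3 (1.68 ± 0.14) and NDUFA2 (1.37 ± 0.13), 4 lower and 34 did not pass, with 39 up and 4 down adjusted over the list alone. The median lay at 0.45 (camera adjusted p = 1.22e-07, and adjusted p = 0.345 with an estimated correlation). Of 75 mitochondrial ribosomal protein genes 27 were higher, among them MRPL33 (1.57 ± 0.16) and MRPL54 (1.11 ± 0.12), 6 lower and 42 did not pass, with 28 up and 6 down adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.000125, and adjusted p = 0.487 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 13 were higher, among them RPS15A (1.68 ± 0.20) and RPL27 (1.39 ± 0.27), 1 lower and 65 did not pass, with 6 up and 1 down adjusted over the list alone. The list had a median of 0.20 (camera adjusted p = 0.0235, and adjusted p = 0.921 with an estimated correlation). This call was lost under quantile normalization (adjusted p = 0.415), with fry (0.530) and without array 1 or 2 of the total untreated group (0.0647 and 0.0688) or array 3 or 4 of the polysomal untreated group (0.0541 and 0.0791).

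In polysomal RNA of untreated cells 27 of 34 genes of G2 and M phase were lower, among them topoisomerase TOP2A (-2.33 ± 0.19), the kinesin KIF11 (-2.02 ± 0.31), the mitotic kinase AURKB (-1.32 ± 0.22) and CENPF (-1.16 ± 0.15). Of the rest 1 was higher and 6 did not pass, with 27 down and 1 up adjusted over the list alone. Members had a median of -0.96 (camera adjusted p = 4.44e-07, and adjusted p = 0.497 with an estimated correlation). Of 40 genes of G1 and S phase 27 were lower, among them the ribonucleotide reductase subunits RRM1 (-1.56 ± 0.17) and RRM2 (-1.5 ± 0.21) and the replication factors MCM3 (-1.30 ± 0.14) and MCM10 (-1.54 ± 0.18). Of the rest 1 was higher and 12 did not pass, with 29 down and 1 up adjusted over the list alone. As a list they had a median of -0.74 (camera adjusted p = 2.34e-07, and adjusted p = 0.296 with an estimated correlation). Of 53 ribosome biogenesis factors 34 were lower, among them the helicase DDX18 (-1.40 ± 0.14), nucleolin, NCL (-0.97 ± 0.12), and RRP12 (-1.77 ± 0.23). Of the rest 2 were higher and 17 did not pass, with 34 down and 2 up adjusted over the list alone. These genes had a median of -0.58 (camera adjusted p = 8.48e-06, and adjusted p = 0.227 with an estimated correlation). Of 27 heat shock and chaperone genes 16 were lower, among them HSPA1A (-1.41 ± 0.12), HSPA9 (-1.36 ± 0.11), DNAJA1 (-1.42 ± 0.14) and HSP90AA1 (-1.11 ± 0.12). Of the rest 2 were higher and 9 did not pass, with 20 down and 2 up adjusted over the list alone. Across the list the median was -0.64 (camera adjusted p = 0.000100, and adjusted p = 0.0977 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases 15 were lower, among them AARS1 (-1.15 ± 0.16) and EPRS1 (-0.92 ± 0.14), and 4 did not pass, with 16 down adjusted over the list alone. The median lay at -0.70 (camera adjusted p = 0.000125, and adjusted p = 0.0977 with an estimated correlation). Of 13 AP-1, NF-kB and inflammatory genes 11 were lower, among them BIRC3, the chemokine CCL2 (at least 3.09-fold), the NF-kB inhibitor TNFAIP3 (at least 2.45-fold) and TNFAIP2 (-1.67 ± 0.21), and 2 did not pass, with 11 down and 1 up adjusted over the list alone. Their median was -1.12 (camera adjusted p = 0.000113, and adjusted p = 0.250 with an estimated correlation).

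**Figure D3:**
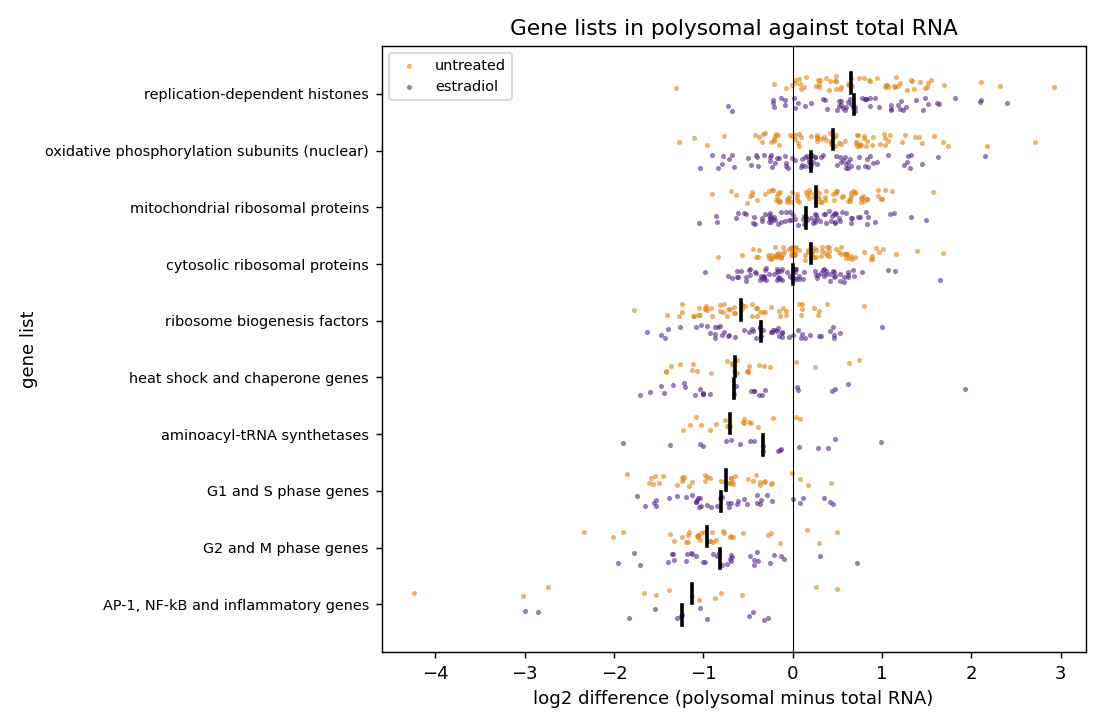
Each point is a gene of 1 of 10 gene lists, with its log2 polysomal minus total difference on the horizontal axis, in untreated cells (orange) and in estradiol-treated cells (purple), and black bars mark the medians. The histone medians lie at 0.66 and 0.68 and those of the G2 and M phase genes at -0.96 and -0.81.

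All these differences are relative to each array's 75th percentile. With the array median subtracted in its place, the median of all genes in untreated cells was 0.24 against -0.09, the split was 4578 higher and 1725 lower, and the lists named kept the sign of their medians. The differences also ran with brightness. Of 8 equal bins of all genes by signal, the dimmest had medians of -0.73 in untreated and -0.64 in estradiol-treated cells. The brightest bin had 0.14 and -0.09. Olfactory receptor genes were looked at after the results were seen. Of 70 tested, 42 were lower and 1 higher in polysomal RNA of untreated cells (median -1.24), against 3298 and 2379 of all 13659 genes.

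The same comparison in estradiol-treated cells describes the relative signal of transcripts in polysomal RNA after 60 min, with the same limit of slide and scan day. LTB was 61.4-fold lower in polysomal RNA (-5.94 ± 0.17, limma adjusted p = 1.97e-12), CFB 37.0-fold lower (-5.21 ± 0.34, adjusted p = 1.84e-07) and SERPINA3 12.5-fold lower (-3.64 ± 0.33, adjusted p = 1.78e-06). KCNQ1OT1, a long non-coding RNA that acts in the nucleus, was 13.4-fold lower (-3.75 ± 0.31, adjusted p = 9.50e-07). CAV1 was 14.8-fold higher (3.89 ± 0.25, adjusted p = 1.84e-07) and NCF2 9.85-fold higher (3.30 ± 0.33, adjusted p = 3.81e-06).

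After estradiol 2867 genes were higher and 3656 lower in polysomal RNA. The other largest positive differences were those of the calcium channel CACNA1E (3.46 ± 0.73), the actin-severing protein SCIN (3.31 ± 0.35), TRIM74 (3.30 ± 0.22), VGLL1 (at least 5.19-fold), the protease inhibitor CST6 (3.21 ± 0.32), the complement receptor C3AR1 (3.12 ± 0.58), the GABA receptor subunit GABBR2 (2.85 ± 0.31) and SLC26A1 (2.73 ± 0.35). The other largest negative differences were those of the olfactory receptor OR2W1 (-3.58 ± 1.06), SULT1C4 (at least 4.25-fold lower), KIR3DL3 (at least 3.17-fold lower), the kinase WNK2 (-3.26 ± 0.31), SLC17A3 (-3.25 ± 0.45) and the T-box factor TBX3 (-3.23 ± 0.38).

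Of the 56 histone genes 40 were higher, 2 lower and 14 did not pass, with the same counts adjusted over the list alone. The list had a median of 0.68 (camera adjusted p = 1.33e-11, and adjusted p = 0.642 with an estimated correlation). Of the 74 genes for oxidative phosphorylation 28 were higher, among them COX7B (2.15 ± 0.22), 11 lower and 35 did not pass, with 28 up and 11 down adjusted over the list alone. Members had a median of 0.20 (camera adjusted p = 0.00154, and adjusted p = 0.778 with an estimated correlation). Of 34 genes of G2 and M phase 23 were lower, among them CENPF (-1.71 ± 0.15) and TOP2A (-1.96 ± 0.19), 1 higher and 10 did not pass, with 24 down and 1 up adjusted over the list alone. As a list they had a median of -0.81 (camera adjusted p = 2.69e-05, and adjusted p = 0.778 with an estimated correlation). Of 40 genes of G1 and S phase 27 were lower, among them RRM1 (-1.74 ± 0.17) and MCM3 (-1.38 ± 0.14), 2 higher and 11 did not pass, with 28 down and 2 up adjusted over the list alone. These genes had a median of -0.80 (camera adjusted p = 2.27e-05, and adjusted p = 0.707 with an estimated correlation). Of 53 ribosome biogenesis factors 22 were lower, among them NOLC1 (-1.48 ± 0.14), 6 higher, among them NHP2 (1.0 ± 0.11), and 25 did not pass, with 23 down and 6 up adjusted over the list alone. Across the list the median was -0.35 (camera adjusted p = 0.0137, and adjusted p = 0.707 with an estimated correlation and 0.0681 without array 1 of the total estradiol group). Of 27 heat shock and chaperone genes 18 were lower, among them HSPA9 (-1.60 ± 0.11), 3 higher, among them HSPB8 (1.93 ± 0.21), and 6 did not pass, with the same counts adjusted over the list alone. The median lay at -0.65 (camera adjusted p = 0.00127, and adjusted p = 0.327 with an estimated correlation). Of 13 AP-1, NF-kB and inflammatory genes 10 were lower, among them the NF-kB inhibitor NFKBIA (-1.29 ± 0.19), and 3 did not pass, with 10 down adjusted over the list alone. Their median was -1.24 (camera adjusted p = 0.000213, and adjusted p = 0.509 with an estimated correlation). Of the lists called in untreated cells 2 did not pass after estradiol. Of 19 aminoacyl-tRNA synthetases 9 were lower, 3 higher and 7 did not pass, with the same counts adjusted over the list alone and a median of -0.34 (camera adjusted p = 0.133, and adjusted p = 0.707 with an estimated correlation). Of 79 cytosolic ribosomal protein genes 8 were higher, 5 lower and 66 did not pass, with 5 up and 1 down adjusted over the list alone and a median of 0.0061 (camera adjusted p = 0.516, and adjusted p = 0.951 with an estimated correlation). Neither list passed in the interaction (adjusted p = 0.174 and 0.230).

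Between untreated and estradiol-treated cells 1598 genes were higher in polysomal RNA in both, 2008 were lower in both and 51 had calls in opposite directions, where independent lists would share 499 and 883 genes. The correlation of both sets of differences across genes was 0.72. Both comparisons hold the same difference in scan day, and both ran with brightness. Their agreement therefore cannot be read as shared loading onto polysomes alone. With the array median subtracted, the median of all genes after estradiol was 0.15 against -0.10, and the split was 4283 higher and 2291 lower.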

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

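Chosen only after the results were seen were the tests of a brightness trend, of signal close to the background, of olfactory receptor genes, of the 4 dimmest arrays, of normexp and of slides for the genes changed in total RNA, those of array spread, of the change under cyclic loess and of slides for the estradiol-induced list, and those of immune cell markers, of list intervals and of scan days for the AP-1 and NF-kB list.

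For each named gene, for further members of the lists described and for 3 measures of each array, the highest or lowest of the 4 arrays of a group was compared with the nearest other array, as the gap between them divided by the range of the group. In 63 of 800 groups this share exceeded the 95% critical value of Dixon's test, which chance alone gives in about 1 of 20 groups. Array 1 of the polysomal estradiol group lay apart for WFDC11 (0.883). For ANTXR2 (0.833), ASB2 (0.894), CXCL12 (0.837), DDX18 (0.955), EGR3 (0.937), H4C2 (0.952), HSPA1A (0.950), KIF11 (0.863), KIF23 (0.937), PCDH10 (0.848), SLC9B2 (0.888) and TOP2A (0.834), it was array 3 of the polysomal estradiol group. C3AR1 (0.900), CACNA1E (0.943), GAS5 (0.928), HIC2 (0.843), MCM3 (0.914), SLC26A1 (0.931), TNFAIP2 (0.858), TXNIP (0.903) and ZNF823 (0.942) set array 4 of the polysomal estradiol group apart. Array 2 of the polysomal untreated group lay apart for CRHR2 (0.936), DUSP1 (0.941), HSPB8 (0.920), MRPL14 (0.850), NDUFA2 (0.890) and POPDC3 (0.856). For HSPA1A (0.875), RPL8 (0.840) and SULT1C4 (0.855), it was array 3 of the polysomal untreated group. MEX3B (0.933), SIAH2 (0.870) and ZNF750 (0.866) set array 4 of the polysomal untreated group apart. Array 1 of the total estradiol group lay apart for RPL36AL (0.848) and SEMA3G (0.913). For HSPB8 (0.839), it was array 2 of the total estradiol group. AHSG (0.835), ESR1 (0.833), H4C6 (0.881), HES1 (0.846), HSP90AA1 (0.841), IARS1 (0.880), KIF11 (0.890), OR2W1 (0.838), PGC (0.834), PTGIS (0.858), PVT1 (0.971) and WNK2 (0.875) set array 3 of the total estradiol group apart. Array 4 of the total estradiol group lay apart for COX7B (0.834). For KCNG3 (0.838), MYO3A (0.842), SMAD6 (0.875) and SPRY1 (0.830), it was array 1 of the total untreated group. AARS1 (0.895) and PTGIS (0.970) set array 2 of the total untreated group apart. Array 4 of the total untreated group lay apart for CD86 (0.867), NDUFB5 (0.884), NR0B2 (0.948), PCDHB1 (0.840), PDE5A (0.863), SERPINA3 (0.853) and TRPC2 (0.904).

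The estradiol response differed between polysomal and total RNA, by limma's test of the interaction, for 39 of these genes. The difference was positive for CCND1 (0.85), CXCL12 (0.80), EGR3 (2.33), FOSL2 (0.98), IGFBP4 (1.23), KCNG3 (2.39), KLF4 (1.03), LCE2B (1.72), LRRC32 (2.29), MAFF (1.30), MRPL2 (1.03), POPDC3 (2.13), RXFP4 (2.50), SMTNL2 (2.46), YARS1 (1.5) and ZNF552 (0.78). It was negative for CGB2 (-2.12), CRHR2 (-1.76), HIC2 (-1.07), LPA (-1.78), MAPK8IP3 (-1.96), MEX3B (-1.43), PCDH10 (-1.49), POMK (-2.75), PTGER4 (-1.65), SIX4 (-1.26) and SLC9B2 (-2.04). For 12 genes at least 1 group had no array well above background, so that the fitted value measures no size: CCL2 (0.91), CDH23 (-3.15), CHRNA1 (3.38), CMKLR1 (-2.78), CNTF (2.56), EDDM3B (2.90), FCRLA (3.70), GJA3 (2.90), NINJ2 (2.56), PCDHB1 (2.98), PGC (-2.44) and SLC9B1 (-2.46). CDH23 was at 0.37 with no filter on dim probes. Signals also appeared in data the report does not use: among 8233 probes without a gene symbol, 786 were called after estradiol in total RNA (514 higher, 272 lower) and 82 in polysomal RNA (81 higher, 1 lower).

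More genes were called after estradiol in total RNA (1475, of which 948 lower) than in polysomal RNA (144). The tables argue against a brightness trend left by the scaling as the whole cause (974 genes called lower under cyclic loess). They also argue against the dim array 3 of the total estradiol group alone (1037 genes without it). Dimness of several arrays stays open (170 genes, 125 of them lower, without the 4 dimmest, 2 of which were total estradiol arrays). Signal close to the background stays open as well. Of 11312 genes well above background on all 16 arrays 6.81% were called lower, against 6.94% overall. Those genes make up most of the 13659 tested, so similar shares cannot decide it. Of 8 equal bins by signal, bin 3 from the dim end had 183 genes called lower and the brightest had 16. The count did depend on single arrays (3310, 468 and 509 without arrays 1, 2 and 4 of total estradiol, 541 to 692 without single total untreated arrays), on array weights (7411, of which 3460 lower) and on the signal (60 in total and 50 in polysomal RNA with normexp and the 75th percentile, 1687 and 119 with normexp and quantile normalization). Signal of genes not known in epithelial cells stays open, since 8 of 70 olfactory receptor genes (11.4%, exact 95% interval 5.07% to 21.3%) were called lower, too few to decide. Another 4 were called higher in total RNA, and 1 was called in polysomal RNA. Slide and group cannot be told apart, as 0 slides held arrays of more than 1 group. A response to estradiol is a further open explanation that no test here separated from the slide. Nor can it be told apart from time and handling, as no group was untreated at 60 min.

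The estradiol-induced list had a larger median response in polysomal than in total RNA, by 0.26 over 44 members, which passed camera at the preset correlation (adjusted p = 0.0252) but not with an estimated correlation (0.988), with fry (0.385) or in 7 fits without 1 array (up to 0.0979). The tables argue against a brightness trend as the cause, as the median under cyclic loess was 0.34 and the mean of the list changed by 0.03 (95% interval -0.089 to 0.15). Spread between arrays stays open: the mean of the list per array differed by 0.31 between both responses, with a 95% interval of -0.028 to 0.64 that holds 0 (0.045 to 0.63 under cyclic loess, above 0), and its SD within groups was 0.0955 in total and 0.194 in polysomal RNA. A difference between slides cannot be told apart from the groups, with 0 slides that held more than 1. A selective loading of these transcripts onto polysomes after estradiol is the open explanation that the design names, and it was not tested apart from the slides.

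The fixed list of 13 AP-1, NF-kB and inflammatory genes was lower in polysomal than in total RNA, with medians of -1.12 before and -1.24 after estradiol, calls that were lost with an estimated correlation (adjusted p = 0.250 and 0.509). The 22 tested NF-kB targets outside the list did not share a difference of that size. Their medians were -0.27 (95% interval -0.73 to 0.13) and -0.22 (-0.82 to 0.21), at percentiles 17.3 and 27.3 of 10000 lists matched in brightness. More of them were called lower than higher (7 against 2 and 7 against 1). The intervals take the genes as independent, so a coordinated difference in NF-kB activity stays open. RNA of immune cells in total RNA was not decided by marker genes. Every sample was of the MCF7 line, and the design names no source of immune cells. Of 14 markers on the array 8 were tested, with medians of -0.55 before and -0.087 after estradiol. They went both ways before and after estradiol: CD19 (-1.83, -1.58), CD3E (-0.98, -0.21), ITGAM (-0.57, -1.98), TYROBP (-0.70, -0.48), CD14 (-0.53, 0.04), FCER1G (-0.19, 0.07), CD79A (0.61, 0.92) and CSF1R (1.66, 0.08). CD19, ITGAM and CSF1R were dim, with mean log2 signals of -4.05, -4.65 and -3.96 in total untreated RNA. Low signal stays open too, from values set beside the list after its result was seen. Of 70 olfactory receptor genes 42 were lower and 1 higher in polysomal RNA of untreated cells, with a median of -1.24. Of 8 equal bins of all genes by signal, the dimmest had medians of -0.73 before and -0.64 after estradiol. Scan day and extraction cannot be told apart from the fraction, since 0 scan days held arrays of both. Poor loading of these transcripts onto polysomes, the difference that the fractions name, stays open and was not tested.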

How the results depend on the processing

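Chosen after seeing the data were normexp on the median signal (the files hold no mean signal, for which it was planned), cyclic loess, the brightness covariate, probes without a symbol and leaving out the 4 dimmest arrays. A slide effect and a scan day block were not fitted, since each slide held 1 group and scan day followed the fraction. The counts were 1475 (total RNA), 144 (polysomal RNA), 326 (interaction), 5677 (fractions, untreated) and 6523 (fractions, estradiol), and the cause of the moves below was not tested. In this order normexp with the 75th percentile gave 60, 50 and 1 and, for the last, 4252. Array weights (0.113 to 4.99) gave 7411, 4094, 7279, 8905 and 10341. An adjusted p under 0.01, a stricter test by construction, gave 227, 77, 43 and 3718. Only the groups compared gave 933 and 75, with fewer arrays to estimate the spread. The brightness covariate gave 230 in polysomal RNA and 1123 in the interaction, where probes above background on all 16 arrays gave 206. Without the 4 dimmest arrays total RNA had 170. Probes without a symbol added, with more features tested, gave 499 in the interaction and 8906 and 9994 between fractions. The correlation of both responses, 0.083, was 0.0068 with normexp and the 75th percentile and 0.054 with normexp and quantile normalization. It was -0.055 with the brightness covariate and -0.21 without the 4 dimmest arrays. Camera called 34 of 145 list tests, 0 with an estimated correlation, and 29 to 42 otherwise. CDH23 in the interaction went from -3.15 to 0.37 with no filter on dim probes.

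Median scaling changed the higher and lower calls from 112 and 32 to 92 and 45 (polysomal RNA) and from 246 and 80 to 184 and 251 (interaction). Array weights turned the majority, with 3951 and 3460 in total RNA (against 527 and 948), 1707 and 2387 in polysomal RNA and 3237 and 4042 in the interaction. With the brightness covariate the interaction had 725 and 398, and at an adjusted p under 0.01 it had 38 and 5. Probes without a symbol gave 949 and 1104 in total RNA and 180 and 24 in polysomal RNA. The interaction had 272 and 161 with the series table and 195 and 110 with normexp and quantile normalization. Of the named calls, 50, 34, 27, 57 and 55 in the order above, 5, 19, 0, 50 and 47 passed with each array left out and under each setting for which they were computed. Single genes were not computed for each probe tested, for the stricter thresholds or with probes without a symbol, and were computed for 144 of the 223 calls on probes above background on all 16 arrays and for 196 with only the groups compared, where the interaction has no fit.

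Leaving out single arrays gave 468 to 3310, 94 to 263, 114 to 1129, 4734 to 6601 and 5681 to 6892 genes, 30 to 36 list calls and a correlation of -0.022 to 0.205. Counts in total RNA were 3310, 468 and 509 without arrays 1, 2 and 4 of total estradiol and 692, 679, 541 and 671 without arrays 1 to 4 of total untreated. Those in polysomal RNA were 263 without total estradiol 3 and 94 without polysomal estradiol 3. In the interaction they were 1129, 121, 657 and 137 without total estradiol 1 to 4, 196 and 141 without polysomal estradiol 1 and 2, 129, 206, 114 and 146 without total untreated 1 to 4, and 720 and 136 without polysomal untreated 2 and 3. The correlation fell below 0 without total estradiol 3 (-0.016), polysomal estradiol 3 (-0.0033) and polysomal untreated 2 (-0.022). Of the 34 list calls 21 passed with each array left out.

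Deviations from the group means correlated at -0.29 to 0.35 between same-numbered arrays, above 0.1 in 12 of 24 pairs, and at 0.225, 0.316, -0.023 and 0.345 for numbers 1 to 4 of the polysomal groups. Not every pair exceeded 0.1, so the numbers were not taken to pair the arrays. Differently numbered arrays of different groups correlated at -0.45 to 0.33, an overlapping range. These values do not decide whether same-numbered arrays share a culture. The replicate block gave 1823, 131, 311, 5888 and 6721 genes and 34 list calls. In depth, 11312 genes were well above background on all 16 arrays by the probe that stood for the gene.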

Other observations

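Of the tests in this part, the count of genes shared with the replicate block and the fits with normexp were chosen only after the results were seen.

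In polysomal RNA after estradiol 3 further lists passed limma's camera test at the preset correlation. Of 13 AP-1, NF-kB and inflammatory genes none passed singly, with 2 up adjusted over the list alone, and the list had a median of 0.26 (adjusted p = 0.0316, 0.683 with an estimated correlation, 0.127 under quantile normalization, 0.187 with normexp, 0.0727 on ranks and 0.380 with fry). That call was lost without array 3 or 4 of the polysomal estradiol group (0.104 and 0.0844) or array 2 or 3 of the polysomal untreated group (0.193 and 0.0932). None of 30 further mRNAs with a 5-prime TOP motif passed, singly or adjusted over the list alone, with a median of 0.20 (adjusted p = 0.0348, 0.917 with an estimated correlation, 0.442 under quantile normalization, 0.0546 with no filter on dim probes and 0.700 with fry). It was lost without array 3 or 4 of the polysomal estradiol group (0.117 and 0.723) or array 1 or 4 of the polysomal untreated group (0.0669 and 0.217). Of 339 zinc finger genes 4 rose, ZNF552 (0.89 ± 0.13), ZNF823 (0.99 ± 0.15), ZNF503 (1.14 ± 0.18) and ZNF750 (1.34 ± 0.21), 335 did not pass, and the counts adjusted over the list alone were the same. The zinc finger list had a median of -0.09 (adjusted p = 0.0145, 0.683 with an estimated correlation and 0.349 with fry), so its called members went against its median. Its call was lost without array 4 of the polysomal estradiol group (0.208) or array 1 or 2 of the polysomal untreated group (0.281 and 0.164).

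Between the fractions of estradiol-treated cells 8 of 20 long non-coding RNAs were higher in polysomal RNA, among them LINC-PINT (1.54 ± 0.18), SNHG7 (1.75 ± 0.23) and SNHG11 (0.90 ± 0.16), 1 was lower, KCNQ1OT1, and 11 did not pass. Adjusted over the list alone the counts were the same, and the median was 0.47 (camera adjusted p = 0.0324, 0.778 with an estimated correlation, 0.0624 under quantile normalization, 0.0605 with normexp, 0.109 without array 1 of the total estradiol group and 0.122 without array 4 of the polysomal estradiol group). Of 75 mitochondrial ribosomal protein genes 28 were higher, among them MRPL12 (1.49 ± 0.15), 8 lower and 39 did not pass, with the same counts adjusted over the list alone and a median of 0.15 (camera adjusted p = 0.0305, 0.778 with an estimated correlation, 0.0883 under quantile normalization, 0.109 and 0.0616 without array 1 or 2 of the total estradiol group and 0.0594 without array 3 of the polysomal estradiol group). Of 20 genes reported to fall with estradiol 1 rose and 2 fell in total RNA, SMAD6 (-0.67 ± 0.14) and SNAI2 (-0.90 ± 0.19), and 17 did not pass, with 2 up and 2 down adjusted over the list alone and a median of -0.10 (camera adjusted p = 0.710, and 0.920 with an estimated correlation).

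Other splits of the same arrays into groups of 4 were tested for each comparison. In total RNA 1 of 35 splits, the real one, gave 1475 or more genes and the highest other gave 2. That is the smallest share that 35 splits can give. Every other split mixed arrays of both slides, so the count cannot tell estradiol from a difference between slides. In polysomal RNA 2 of 35 splits gave 144 or more genes, so that chance is not excluded by this count. The other of these, with 431 genes, set arrays 1 and 2 of both polysomal groups against arrays 3 and 4, which points to a structure among the polysomal arrays. The 75th percentiles of arrays 1 and 2 were 2597 and 2507 with estradiol and 1742 and 3018 untreated. Those of arrays 3 and 4 were 780 and 718 with estradiol and 1968 and 873 untreated. Replicate number was also the position on the slide, so sample and position cannot be told apart. With a block on the replicate number 131 genes were called, and 119 of these were among the 144. For the interaction 1 of 100 splits, the real one with 326 genes, was as large (99 others drawn, highest 92). For the fractions only the real split was as large in untreated cells (5677 genes, highest other 74, 1 of 35). The same held in estradiol-treated cells (6523 and 473, 1 of 35). The mixing of slides limits these counts in the same way.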
